A study of Drosophila melanogaster and Drosophila simulans with 21 samples.

How the data were processed

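RNA of whole adult females was compared on spotted cDNA arrays that hybridise 2 labelled cDNAs at once. The flies were the Canton S strain of Drosophila melanogaster, the Sim-1 strain of its sibling species Drosophila simulans, and hybrid daughters of Canton S mothers and Sim-1 fathers. Per the labels, stocks were kept at 25 C and crosses were made at 18 C with 7 to 8 flies of each sex. Virgin females of both species and hybrid females were held for 5 to 6 days at room temperature and frozen within a daily window of 2 hours. Each cross was represented by 2 cohorts, but the separate extractions were mixed into a single RNA pool per strain before poly-A selection. The cDNA was made with amino-allyl dUTP and coupled to Cy3 or Cy5.

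There were 21 arrays. Each of the 3 pairs of RNA was hybridised on 6 arrays, 3 in each channel orientation, and 3 further arrays carried a single RNA in both channels. Replicate numbers within a group follow the order of deposition and pair nothing across groups. Because each strain is represented by 1 pool, the arrays are technical repeats and every p-value measures the spread between arrays only. A difference between strains and a difference between their pools cannot be told apart in this design.

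The authors deposited a table with 1 linear ratio per probe position and array. Scanner, background correction, normalization and spot filters are not given in the sources used here, and channel intensities were not used here, so signal over background is unknown. The number of arrays limits the precision. The deposited ratio had a median of 0.852 to 1.11 per array. Of 6101 probe positions, 1145 held no value on any array. The platform annotation gave 1 gene symbol for 1943 positions, several for 67 and none for 4091, and only positions with 1 symbol were named. Symbols were updated through a gene table of the Release 6 plus ISO1 MT assembly, which also gave locus tags and chromosomes. Positions without a symbol were tested and counted but are not named.

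Ratios were put on the log2 scale. A rule set before the data were examined called for subtracting each array's median if any lay over 0.1 from 0, and 8 arrays did. Higher and lower are thus relative to the median position of an array. Where most genes differ, near-even numbers of higher and lower genes follow largely from this step. Probes of a gene were averaged, which concerned 69 tested genes. A gene or position was tested if it had at least 4 of 6 values in each comparison, which left 4753, of which 1384 were named genes. Below, genes and unnamed positions are counted together unless named genes are specified. Of their values on the 18 arrays with 2 RNAs, 1.43% were missing.

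All 18 arrays entered 1 linear model with limma 3.58.1 in R 4.3.3. It had coefficients for D. simulans and hybrid RNA against D. melanogaster RNA and a channel term per gene. Moderated tests were two-sided, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. The residual degrees of freedom were at most 15, with 4.26 from the prior. The contrasts were D. simulans minus D. melanogaster, hybrid minus each parent, and hybrid minus the mean of both parental log2 levels. The hybrid was counted outside both parents where both of its contrasts passed the threshold with one sign.

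The labels do not say which channel is the numerator. Arrays with swapped channels correlated from -0.93 to -0.46 across positions, so the deposited values follow the channels. The 3 comparisons closed to a loop with an SD of 0.19, against 0.87 with 1 comparison turned, which settles the relative directions but not the overall sign. A rule set before the data were examined assumed channel 2 over channel 1 and allowed the direction to be called likely only if 2 anchors pointed to channel 2 over channel 1 as well. They did not: both favoured channel 1 over channel 2. In that reading, 69 of the 95 genes with the largest parental ratios (72.6%) were higher in D. melanogaster, from which the probes come. This share was 54.5% among the top 20% and 46.7% over all genes. The other anchor presumed that females of this cross are sterile with underdeveloped ovaries, so that germline genes would be lower in the hybrid. With channel 1 over channel 2, the 5 measured germline genes had lower values in the hybrid, with a median log2 of -0.75 against the parental mean. However, ovo and Fs(2)Ket lay near 0 at -0.02 and -0.05. The median gene, c(3)G, differed from D. melanogaster alone and stood at 0.14 against D. simulans. Against D. simulans the list median was -0.04, with 2 members called lower and 1 higher. The condition for calling the direction likely was therefore not met. Channel 1 over channel 2 was adopted after the data were seen, and in the other reading every sign turns. Numbers of genes that differ, sizes of differences and the number outside both parents do not depend on it. Words such as higher and lower below hold in the adopted reading.

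Named genes were picked by a rule set before the data were examined: per contrast the 8 largest rises and 8 largest falls among named genes past the threshold, excluding those known only by CG number, of one sign on all arrays comparing those 2 RNAs. The same number per side was taken for genes outside both parents, by the smaller of both changes. For a gene list past its test, the 4 members with the smallest p were added. Of 9 genes fixed in addition (Yp1, Yp2, Yp3, Adh, vas, osk, nos, Hmr and Lhr), 0 were among the named genes tested. Whether any lies at a position without a symbol is unknown.

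Before the data were examined, 21 gene lists were fixed, among them markers of tissues that whole females could hold in different amounts. Each list with at least 4 measured members, 11 in all, was tested with limma's camera at a preset correlation of 0.01 in 4 contrasts, and the 44 p-values were adjusted together. The lists were covered only in part. Measured under a symbol were 12 of 46 fat body genes, 5 of 37 muscle genes, 4 of 48 DNA replication genes and 5 of 91 germline genes. Counts of list members below refer to measured members. The symbol pattern placed Cyp1, a cyclophilin, in the list of cytochrome P450 genes, and an old synonym placed tant in the cuticle list. Lists drawn up after the results were seen are named as such. X-linked and autosomal genes were compared with two-sided Fisher's exact tests. A test by cDNA library of origin was planned and not run, since probe identifiers here are positions. Outlying arrays were sought with Dixon's ratio at 0.625 for 6 arrays and 0.71 for 5.

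The alternatives changed 1 choice at a time: deposited medians, arrays scaled to a common spread, no channel term, the self-self arrays included, other limits on missing values, direct arrays only, title number as a random block, arrays averaged per comparison, single probes, robust moderation, stricter thresholds, each array left out, an estimated inter-gene correlation, and the fry test. Separate channel terms for arrays with title numbers 1 to 8 and 14 to 18, each of these series alone, and the lists without Cyp1 and tant were added after the data were seen.

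The model was tested on simulated data with 4753 genes. For hybrid minus D. melanogaster, 42% of genes changed by 0.3 log2 units were recovered, 86% of those changed by 0.5 and 100% of those changed by 1. For D. simulans minus D. melanogaster the shares were 56%, 86% and 100%, and for levels outside both parents 36%, 80% and 100%. False calls made up 1.68%, 6.04% and 0% of the simulated calls, in that order. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.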

Results

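Transcript levels of whole virgin females were compared between D. melanogaster Canton S, D. simulans Sim-1 and their F1 hybrid daughters, with 6 arrays for each pair of RNA pools and 3 arrays with the same RNA in both channels. Every array held values for 4657 to 4946 probe positions. The 3 comparisons ask how the parental species differ and where the hybrid level lies relative to each parent.

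The self-self arrays gave the technical background. Their log2 ratios had an SD of 0.209 to 0.215, and 0.311% to 0.629% of positions exceeded 2-fold. Arrays of D. melanogaster against D. simulans had SDs of 0.434 to 0.763. Arrays with hybrid RNA spread most, from 0.895 to 1.18 against D. melanogaster and from 0.979 to 1.25 against D. simulans. The share of positions over 2-fold was 26% to 37.3% and 27.0% to 39.8% on those arrays, and 3.46% to 14.6% between the parents.

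**Figure D1:**
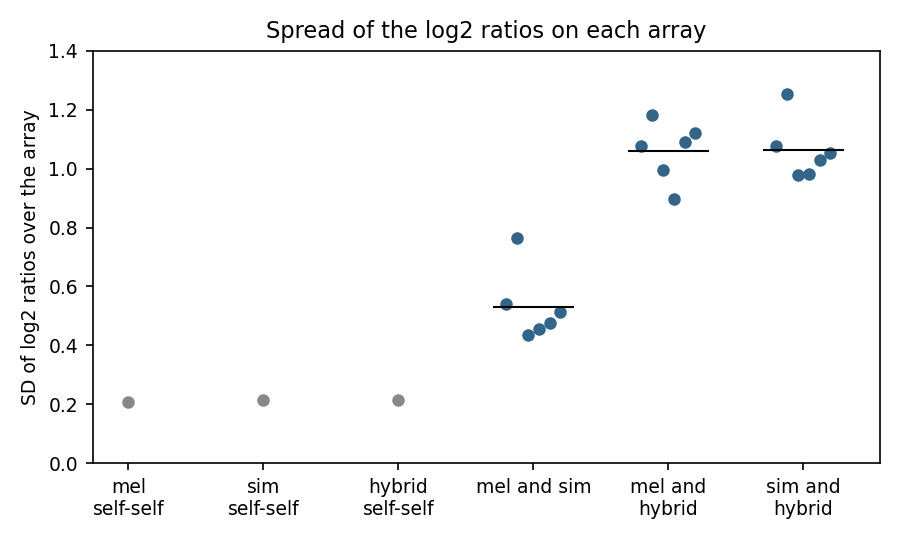
Each point is the SD of the log2 ratios over 1 array, by the RNAs hybridised (mel, D. melanogaster; sim, D. simulans), with the mean over 6 arrays as a line. The 3 self-self arrays lie at 0.209 to 0.215, below all 18 others, and 1 array of mel and sim stands apart at 0.763.

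The labels do not state the numerator of the ratios. Signs are given with channel 1 over channel 2, a reading adopted after the data were seen because both preset anchors favoured it, although the preset rule had assumed the opposite. In the other reading every rise below is a fall and every fall a rise, while all sizes and totals stay.

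In the adopted reading of the ratios, D. simulans RNA gave less signal than D. melanogaster RNA for tkv (CG14026), a type I receptor of the BMP pathway. The log2 value was -2.30 ± 0.13 (SE, 6 of 6 arrays, 4.91-fold). The synaptonemal complex gene c(3)G fell by 1.78 ± 0.19 on the log2 scale and gkt, which encodes a tyrosyl-DNA phosphodiesterase, by 1.28 ± 0.089. An anchor of the sign presumed lower D. simulans signal among the largest ratios, because the probes come from D. melanogaster. For these falls, probe mismatch and expression were therefore not told apart. Levels were higher in D. simulans for Sgp (CG13091) at 1.80 ± 0.12, the formin gene Fhos at 1.55 ± 0.14, Arc1, a Gag-like gene of neurons, at 1.46 ± 0.16, and the glutathione transferase gene GstE13 at 1.31 ± 0.071. Direct array means with their SD were -2.27 ± 0.44 for tkv and 1.75 ± 0.41 for Sgp (n = 6 each).

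Other rises in D. simulans were Nepl3, a neprilysin-like gene, at 1.26, yip7 at 1.22, the caspase gene Strica at 1.15 and the dynein light chain gene Cdlc2 at 1.10. Further falls were the mucin gene Muc68D at -1.13, the galactosyltransferase gene C1GalTA at -1.08, Phf7, a histone reader of the male germline, at -1.05, Stlk at -1.02 and orion at -0.996. Adjusted p-values of these 16 genes ran from 1.44e-12 for Strica to 1.08e-05 for Cdlc2. The gene c(3)G was measured on 5 direct arrays, and the others on 6. Single direct arrays lay apart from the rest for Sgp, Nepl3, tkv, Muc68D and C1GalTA.

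Over all genes tested, 2223 of 4753 (46.8%) differed between the parents, 1105 higher and 1118 lower in D. simulans. Most of these differences were under 2-fold: 158 genes passed with at least 2-fold, 53 higher and 105 lower. Over all 4753 genes, called or not, the median absolute log2 value was 0.21. Of the 11 preset gene lists, 0 passed camera here (lowest adjusted p = 0.134), 2 had an unadjusted p under 0.05, and 3 passed fry. Germline genes had 3 of 5 members lower in D. simulans, both over all genes and adjusted over the list alone (mei-P26, c(3)G and Fs(2)Ket). Muscle genes had 2 of 5 higher by both counts, Strn-Mlck at 0.99 and up at 0.51. Requiring 1.5-fold reduced the total to 530, of which 62.5% were lower. This excess among large differences restates an anchor of the adopted sign and is no independent evidence of direction. Scaling the arrays to a common spread raised the size of 12 of the 16 named differences by over 1.5 times. Such scaling widens the parental arrays, which spread less than those with hybrid RNA, so this rise follows from the method. The same scaling raised the total to 2962 genes. With title numbers 14 to 18 alone, Phf7 stood at -0.70. Probe mismatch with D. simulans sequence lowers its signal by itself and was not separated from expression.

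Against their maternal species D. melanogaster, and in the adopted reading, hybrid females had far less RNA of BigH1 (CG3509), the linker histone of germline and early embryo, at log2 -4.66 ± 0.23 (SE, 6 of 6 arrays, 25.2-fold). Next among the named genes, Incenp, a subunit of the chromosomal passenger complex, stood at -3.22 ± 0.19, the Aurora A activator gene bora at -3.08 ± 0.15, the meiotic checkpoint gene pch2 at -2.99 ± 0.15 and the spindle orientation gene mud at -2.97 ± 0.16. Levels rose for Sgp, at 3.34 ± 0.12 (10.1-fold), and Arc1, at 2.80 ± 0.16. Rises were also found for the apolipophorin precursor gene apolpp, at 2.57 ± 0.12, the lipase gene mag at 2.54 ± 0.11, and the fatty acid synthase gene FASN1 at 2.51 ± 0.13.

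The remaining falls of the largest 8 were APC7, a subunit of the anaphase-promoting complex, at -2.91, RnrL, the large subunit of ribonucleotide reductase, at -2.80, and the mitotic kinase gene gwl at -2.67. The remaining rises were yip7, a serine protease gene, at 2.50, vanin-like at 2.08 and the cytochrome P450 gene Cyp4ac1 at 1.99. Adjusted p-values ran from 7.69e-15 for Sgp to 2.72e-09 for RnrL. Direct arrays averaged -4.44 ± 1.05 for BigH1 and 3.39 ± 0.43 for Sgp (SD, n = 6), and single arrays lay apart for BigH1 and gwl. In total 3983 genes (83.8%) differed, 1996 higher and 1987 lower in the hybrid. This near-even split, like those of the other hybrid contrasts below, follows largely from subtracting the array medians. At least 2-fold differences numbered 1411, with 715 higher and 696 lower. Scaling the arrays to a common spread, which narrows arrays with hybrid RNA, reduced vanin-like to 1.32 and bora to -2.03. Requiring 1.5-fold left 2643 genes. With deposited medians 54.8% of differing genes were lower instead of 49.9%.

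Against their paternal species D. simulans, in the same adopted reading, hybrid females again had, among the named genes, the lowest relative level for BigH1, at log2 -4.33 ± 0.23 (SE, 6 of 6 arrays). Next came bora at -3.71 ± 0.15 (13-fold), Incenp at -3.09 ± 0.19, mud at -2.82 ± 0.16 and gwl at -2.74 ± 0.21. Higher levels were found for apolpp at 2.93 ± 0.12 (7.64-fold), mag at 2.79 ± 0.11, vanin-like at 2.54 ± 0.15 and Muc68D at 2.34 ± 0.11. The virus-induced gene vir-1 rose by 2.30 ± 0.11, and regucalcin, named for its calcium-binding product, by 2.25 ± 0.096.

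The P450 gene Cyp12d1-p stood at 2.12, although its probe can also bind the closely similar copy Cyp12d1-d, and the serine protease homologue gene sphe at 1.89. The kinase gene S6KL stood at -2.66, rdx, which encodes a substrate adaptor of ubiquitin ligase, at -2.64, and the stathmin gene stai at -2.54. Adjusted p-values ran from 5.99e-16 for S6KL to 1.95e-10 for gwl. Direct arrays averaged -3.77 ± 0.64 for bora and 3.14 ± 0.51 for apolpp (SD, n = 6), and 1 array lay apart for mud. Altogether 3908 genes (82.2%) differed, 1971 higher and 1937 lower in the hybrid, with 658 higher and 629 lower at 2-fold or more. With deposited medians the median gene lay at -0.10 in this contrast instead of 0.02, and 56.6% of differing genes were then lower instead of 49.6%. Requiring 1.5-fold left 2464 genes.

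In the adopted reading, hybrid levels lay outside the range of both parents for apolpp, mag, vanin-like, sphe and regucalcin on the high side, and for BigH1, Incenp, bora, mud and gwl on the low side. In the hybrid, sphe was higher than D. melanogaster by 1.92 ± 0.074 and than D. simulans by 1.89 ± 0.074 on the log2 scale. The neprilysin-like gene Nepl21 was higher by 1.78 and 1.66, Sec16, which acts at endoplasmic reticulum exit sites, by 1.62 and 1.63, and the aldehyde dehydrogenase gene Aldh7A1 by 1.602 and 1.857. On the low side, rdx stood at -2.61 and -2.64, S6KL at -2.53 and -2.66, and CG12109, the gene of the large subunit of chromatin assembly factor 1, at -2.46 against each parent. On the arrays with D. melanogaster, 1 array lay apart for rdx.

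**Figure D2:**
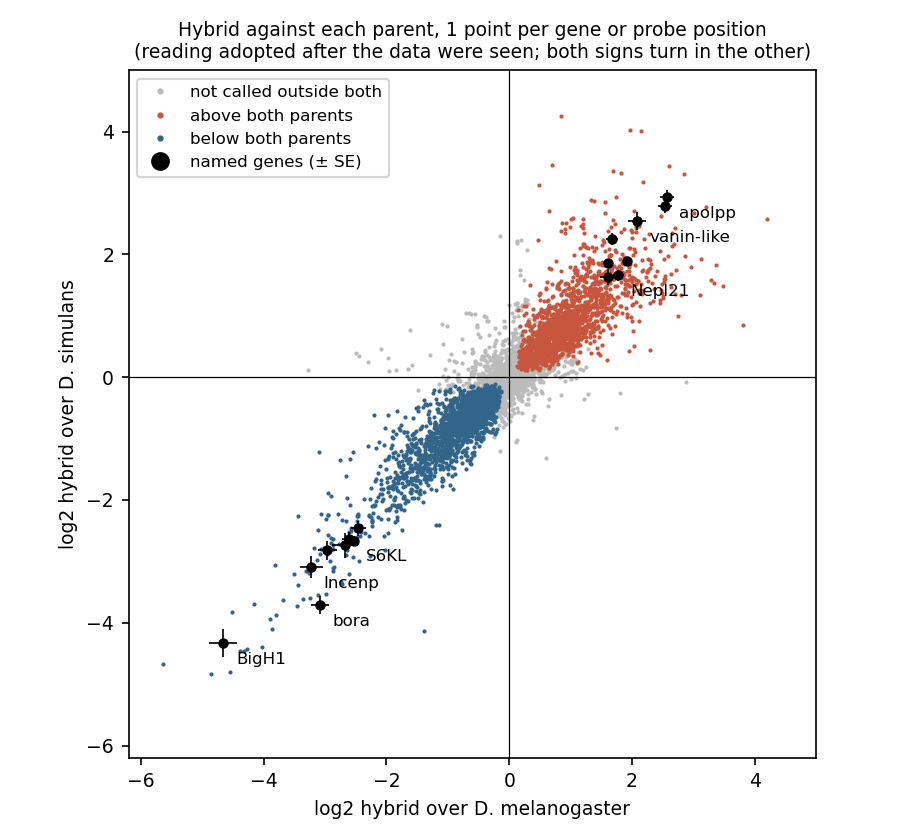
Each point is 1 of 4753 genes or probe positions, with the log2 ratio of hybrid over D. melanogaster (adopted reading) on the x axis and over D. simulans on the y axis, and named genes in black with their SE. The 1711 genes above both parents and the 1721 below both lie along the diagonal, with BigH1 at -4.66 and -4.33 far down and apolpp at 2.57 and 2.93 far up.

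In all, 3432 genes (72.2%) were outside both parents, 1711 above and 1721 below. Of these, 505 were above and 517 below by over 2-fold from both, and 27 and 101 by over 4-fold. Between the parents and apart from both were 105 genes, including Fs(2)Ket. Another 446 differed from D. melanogaster alone, 371 from D. simulans alone and 399 from neither. The share outside both was 69.0% where the parents differed and 75.0% where no parental difference was called. Relative to the parental mean, 4052 genes differed, 2043 higher and 2009 lower. Requiring 1.5-fold against each parent left 2097 genes outside both, and 2559 apart from the mean. Scaling the arrays to a common spread left 2505 outside both. With deposited medians, 57.0% of the genes outside both and 55.4% of those apart from the mean were lower. With the 6 arrays of each pair averaged to 1 value first, the error came only from how well the pairs close to a loop. The spread between arrays was dropped and no repeat of the pools was added, so counts from that fit are not given here.

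Both hybrid contrasts share the hybrid pool. Across genes, which are not independent replicates, they correlated at 0.908 with a covariance of 0.924. Simulated unchanged groups gave a mean correlation of 0.4996, a covariance of 0.00599 and 0 genes outside both parents in 20 simulations. The covariances differed by 0.918. The simulations held array error only and no difference between pools, so they show only what array error yields. Independent lists of these lengths would share 828 higher and 810 lower genes, against 1711 and 1721 observed. Estimates from separate arrays for each parent correlated at 0.901 with a covariance of 0.921, but the same hybrid RNA was on both sets. A deviation of that single pool would also give a high covariance, so these values do not tell it from a difference of the hybrid.

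In the adopted reading, genes of fat body storage and lipid metabolism were higher in the hybrid than the parental mean in 12 of 12 measured members (46 listed). This held both over all genes and adjusted over the list alone. The largest were apolpp at log2 2.75, FASN1 at 2.04, regucalcin at 1.96 and fbp, which encodes fructose-bisphosphatase, at 1.39. The list median was 0.92 (camera adjusted p = 0.0106). That call was lost with adjusted p = 0.346 with an estimated correlation. Against D. melanogaster 11 of 12 were higher (12 adjusted over the list alone; median 0.96, adjusted p = 0.0106), with Glyp, glycogen phosphorylase, at 0.99. Against D. simulans 11 of 12 were higher by both counts (median 0.91, adjusted p = 0.0125), with fbp at 1.79. Each was lost at adjusted p = 0.346 with an estimated correlation, and among genes measured on all 18 arrays the adjusted p was 0.0610, 0.0610 and 0.0790 for the mean, D. melanogaster and D. simulans. Scaling the arrays to a common spread, which narrows arrays with hybrid RNA, kept the call. It reduced the median to 0.58 against D. melanogaster and 0.61 against D. simulans. With title numbers 1 to 8 alone the median was 0.60 against D. melanogaster.

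No other preset list passed camera against the parental mean in the main model, although under other settings the detoxification list passed in 13 of 34, muscle in 13 of 33 and DNA replication in 9 of 34. For these 10 lists the counts adjusted over the list alone equalled those over all genes. Muscle genes were higher in 5 of 5 members, including Prm at 1.34 and Zasp66 at 1.13 (median 1.02, adjusted p = 0.0512). Of the detoxification genes, 8 of 10 were higher, such as GstE12 at 1.65 and GstZ2 at 1.36, and the P450 gene Cyp6u1 and the cyclophilin gene Cyp1 were lower (median 1.21, adjusted p = 0.0512). Cuticle and chitin genes were higher in 6 of 7, among them obst-A at 1.41, with tant lower at -1.27 (adjusted p = 0.180). Vision genes were higher in 3 of 4, led by Galphaq at 1.13 (adjusted p = 0.294), and synaptic and excitability genes in 4 of 7, led by the channel gene slo at 1.13 (adjusted p = 0.410).

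All 4 measured DNA replication genes (48 listed) were lower than the parental mean, RnrL at -2.51, CG12109 at -2.46, Prim2 at -2.12 and PolE1 at -1.59 (median -2.29, adjusted p = 0.0544). Proteasome genes were lower in 4 of 5, including Rpt5 and Rpn1 at -0.74 each (adjusted p = 0.134), and chaperone genes in 3 of 4, with CCT5 at -1.40 (adjusted p = 0.221). Germline genes were lower in 3 of 5, with zuc, a piRNA pathway nuclease, at -1.74 (adjusted p = 0.294). This list served as an anchor of the sign and is no independent evidence of its direction. Among ribosomal protein genes 1 of 4 was higher, RpS12 at 0.23 (adjusted p = 0.792), and their median of 0.06 became -0.055 with deposited medians. Without the misplaced Cyp1 and tant, an alternative added after the data were seen, the detoxification, muscle, cuticle and DNA replication lists passed, with adjusted p of 0.0180, 0.0448, 0.0455 and 0.0455. With an estimated correlation 0 lists passed, whereas 10 of 11 passed fry, which does not compare a list with other genes.

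**Figure D3:**
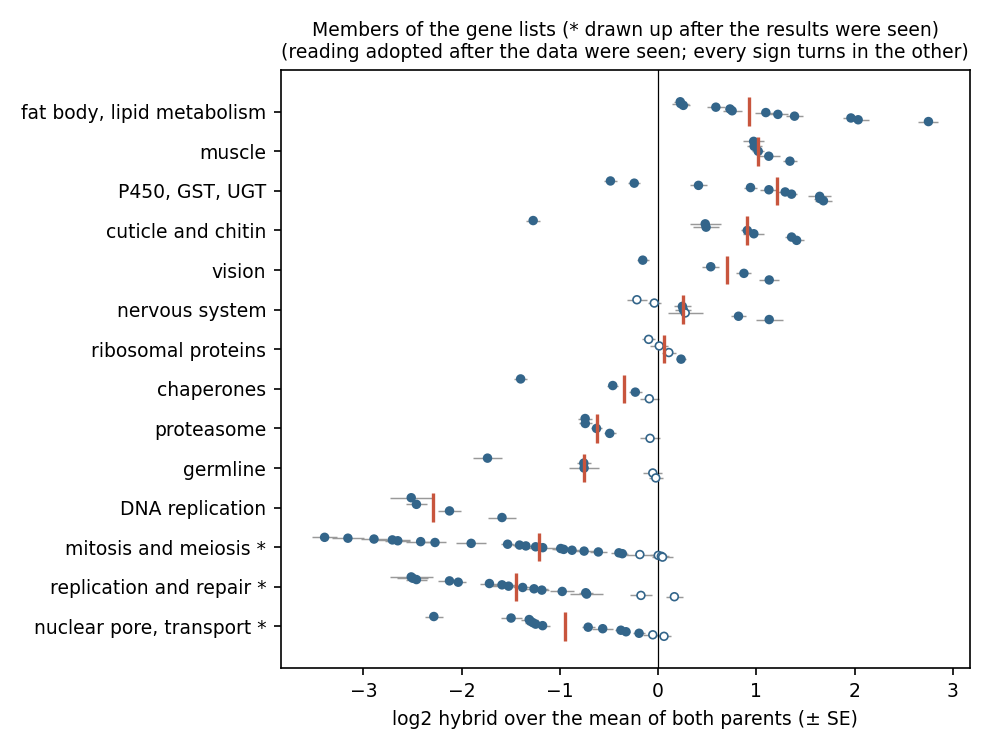
Each point is a gene's log2 level in the hybrid relative to the mean of both parents (x axis, ± SE, adopted reading), grouped by list on the y axis, filled where its adjusted p was under 0.05, with the list median as a red bar. All 12 measured fat body genes lie above 0 around a median of 0.92, and all 4 measured DNA replication genes lie below 0 around -2.29.

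The other 10 preset lists had fewer than 4 measured members and were not tested. Eggshell, dorsoventral patterning, yolk and immune lists had 0 under a symbol, and members at positions without a symbol would be missed. Against the parental mean, the digestive genes mag and yip7 stood at 2.67 and 1.90, and the odorant-binding gene Obp19d at 1.59. The respiratory chain gene ND-51 stood at 1.17, and the glycolysis and citrate cycle genes Ogdh, Pfk and Scsalpha1 at 1.03, 0.93 and 0.69. Of 2 testis genes, ocn stood at 0.70 (adjusted p = 0.00285) and janB at 0.32 (adjusted p = 0.0943). In the chromatin and incompatibility list, BigH1 stood at -4.49 and Nup98-96 at -1.25.

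In the adopted reading, X-linked genes such as mud, APC7, S6KL and CG12109 were among the largest falls in the hybrid. Below D. melanogaster were 131 named X-linked genes (51.4%) and 457 autosomal ones (40.5%; odds ratio 1.55, 95% interval 1.17 to 2.06, Fisher's exact adjusted p = 0.0119 over 12 tests). Below both parents were 45.5% and 35.0% (odds ratio 1.55, adjusted p = 0.0119), and below D. simulans 48.6% and 39.9% (odds ratio 1.42, adjusted p = 0.0411). D. simulans lay below D. melanogaster for 29.0% and 21.5% (odds ratio 1.49, adjusted p = 0.0411). With deposited medians these adjusted p-values rose to between 0.0947 and 0.0960, and genes are not independent in these tests. The odds against D. simulans and those between the parents passed in 18 of 34 other settings each. With title number as a random block both lost their call (Fisher's exact adjusted p = 0.0543 and 0.0746).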

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

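Of the tests in this part, those of channel, array series, ovary share, probe mismatch, X-linked list genes and the deviating array were chosen after the results were seen, and the reassignments of arrays were set before the data were examined.

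For 12 of 70 groups of arrays, 1 array lay further from its nearest neighbour than Dixon's ratio allows. Chance alone flags about 1 in 20 groups, here 3.5. Signs below are in the adopted reading. On arrays of D. melanogaster and D. simulans, Sgp stood at 0.94 on array 4, with the other 5 at 1.73 to 2.02, and tkv at -1.44 on array 3, against -2.61 to -2.23. On array 2, Nepl3 stood at 0.68 (others 1.29 to 1.47), Muc68D at -0.66 (others -1.26 to -1.08) and C1GalTA at -0.64 (others -1.18 to -1.06). On arrays of D. melanogaster and hybrid, BigH1 stood at -2.36 (others -5.33 to -4.62) and rdx at -1.36 (others -2.91 to -2.63) on array 4, and gwl at -3.94 on array 5 (others -2.49 to -1.78). On arrays of D. simulans and hybrid, mud stood at -2.10 on array 3, with the others at -3.22 to -2.87. The SD over the array was 0.763 on array 2 of the parents (others 0.434 to 0.540) and 1.25 on array 2 of D. simulans and hybrid (others 0.979 to 1.08). Array 3 of the parents held 4946 values, the others 4815 to 4862.

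The parental difference could rest on array 2 of the parents, whose spread was widest. Its correlation with the other 5 across genes was 0.304 to 0.622, against 0.644 to 0.962 among those. Without it 2208 genes differed, 2005 of them also called with the same sign when it was included, so the total did not rest on this array. Of 100 assignments of the 18 arrays, the real one included, 2 called as many genes as the real 2223, and the highest other reached 2495. The assignments mixed arrays of different pairs, whose spreads differ, and the arrays repeat the same pools. They therefore cannot decide whether the parental difference arose by chance. The other assignment shows that the structure of the arrays can yield large numbers.

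Hybrid levels outside both parents could come from the channels, from 1 series of arrays, or from less ovary in hybrid bodies. A channel effect would make arrays with swapped channels correlate above 0 over all positions, but those with hybrid RNA correlated at -0.79 at most, and 92.5% of the genes outside both in the smaller of the series (title numbers 1 to 8 and 14 to 18) lay outside on the same side in the other. Less ovary would raise alike only those transcripts that the ovary lacks, and ovary levels of these genes were not measured. An uneven rise is therefore no evidence against it. Of 35 members of 5 somatic lists (tant included), 30 were higher than the parental mean, 2 lower and 3 not called. They ran from -1.27 to 2.75, with an SD of 8.67 times the median SE, which measures array error only. In the last of 3 tests tried, the tissues had medians of 0.26 to 1.02. They did not differ beyond the spread of their members without tant (permutation test of the Kruskal-Wallis statistic, p = 0.111). The sign was adopted partly from germline genes, on the premise that females of this cross have underdeveloped ovaries. A smaller ovary share is thus presumed by that anchor, and these values by themselves neither exclude nor show it. In 100 assignments, 1 each (the real one) reached 3432 genes outside both (highest other 0), 3983 against D. melanogaster (2637), 3908 against D. simulans (2535) and 4052 against the parental mean (2537). These totals thus depend on the labelled arrangement of the arrays. Because the assignments mixed arrays of different pairs that repeat the same pools, they decide nothing about chance differences between pools.

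The lower levels of X-linked genes in the hybrid could reflect mismatch between probes and D. simulans sequence, or the X-linked members of lists drawn up after the results were seen. Whether a smaller ovary share contributes was not tested for these genes. Mismatch alone would leave the hybrid, with 1 X of each species, at or above D. simulans. The odds of lower calls against D. simulans were 1.42 on the X, but passed the threshold in 18 of 34 other settings. The prediction also depends on the sign. In the other reading the calls given here as higher, with odds of 0.81 on the X, would be the lower ones. The data therefore cannot tell. Left out next were 77 genes of the lists of mitosis and meiosis, replication and repair, nuclear pore and transport, splicing and 3' processing, and aminoacyl tRNA synthetases. The odds of lying below both parents were then 1.62 (95% interval 1.21 to 2.18). With 10 X-linked genes left out they could not have fallen under 1.29, so this test decides nothing and the explanation by list members stays open.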

How the results depend on the processing

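Settings that separate or select the title-number series, lists without Cyp1 and tant, and the residual correlations of arrays were chosen after the results were seen. All 67 effects of the 42 named genes kept direction and call in every setting that gave a value, and 11 lacked a value in some setting. Their log2 values ranged from 0.488 to 1.69 times the main ones. Most of these genes were picked for large called effects, and those picked per contrast also for one sign on all direct arrays. Their stability in fits of the same arrays thus follows largely from the selection and does not extend to other genes. The counts of differing genes stayed within 1.5 times in 165 of 170 cases. Within that limit, scaling the arrays to a common spread gave 2962 genes between the parents and 2505 outside both, against 2223 and 3432 in the main model. Title numbers 1 to 8 alone gave 1611 and 2999, and 14 to 18 alone gave 2858 and 3689. With 1 array left out the counts were 1977 to 2359 between the parents, 3920 to 4041 against D. melanogaster, 3806 to 4018 against D. simulans, 3986 to 4112 against the parental mean and 3346 to 3524 outside both. Requiring 1.5-fold left 530, 2643, 2464, 2559 and 2097, which follows from the added requirement. With all signs turned, the germline median became 0.75. No paired analysis was possible because replicate numbers follow the order of deposition, and 7 of the 8 pairs of arrays with 1 title number belong to a single comparison. With title number as a random block (correlation 0.159) the counts were 2221, 4008, 3894, 4066 and 3430, and 2 X-linked results given below lost their call. Of 16 arrays that share a title number, 6 had their highest residual correlation with the array of the same number. Signal over background was not analysed here, and the test by cDNA library was not run.

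The fat body list lost its call among genes measured on all 18 arrays, which has fewer members, with medians of 0.93, 0.71 and 0.75 against D. melanogaster, D. simulans and the parental mean. It also lost it with an estimated correlation, at medians of 0.96, 0.91 and 0.92. Over all settings the medians ran from 0.58 to 1.19, 0.61 to 1.14 and 0.66 to 1.21. For the other lists, camera results kept their side of the threshold in 1265 cases and gained a call in 87, and fry, which does not compare a list with other genes, gained 30.

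The X-linked odds lost their call in 40 cases, and the cause was not tested. For contrasts A (D. simulans against D. melanogaster), B (hybrid against D. melanogaster), C (hybrid against D. simulans) and D (below both parents), they were 1.49, 1.32, 1.35 and 1.39 with deposited medians, 1.498, 1.45, 1.35 and 1.46 with title numbers 1 to 8, and 1.37, 1.49, 1.22 and 1.25 with 14 to 18. For A, C and D they were 1.37, 1.05 and 1.29 with scaled arrays and 1.32, 1.46 and 1.43 at 1.5-fold. For A and C they were 1.403 and 1.41 without a channel term, 1.41 and 1.42 with title number as a block (adjusted p = 0.0746 and 0.0543), and 1.31 and 1.32 at adjusted p under 0.01. For C alone they were 1.31 with direct arrays and 1.28 with separate channel terms. With 1 array left out, A ranged from 1.33 to 1.57 and C from 1.35 to 1.47.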

Other observations

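The gene lists and tests in this part were chosen after the results were seen, so their p-values do not count as independent tests. In the adopted reading, genes of mitosis and meiosis were lower in the hybrid than in D. melanogaster in 20 of 24 cases, with 0 higher and the same numbers adjusted over the list alone. Beyond the genes named above, Zwilch, a kinetochore checkpoint gene, stood at log2 -2.29, ana2, needed for centriole duplication, at -1.86, and APC4 at -1.35. The list median was -1.28 (camera adjusted p = 1.29e-04), but the call was lost with adjusted p = 0.0911 with an estimated correlation. Of 16 genes of DNA replication and repair, 14 were lower by both counts, including the helicase genes Pif1 at -2.66 and RecQ4 at -1.94 and the polymerase gene PolH at -1.80 (median -1.73, adjusted p = 5.46e-04, and adjusted p = 0.205 with an estimated correlation). Since large falls of such genes prompted the lists, their direction is no independent finding.

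Nuclear pore and transport genes were lower in 13 of 14 cases against D. melanogaster by both counts, and 1 was higher when adjusted over the list alone. Among them were Nup93-1 at -2.23, the GTPase gene Ran at -1.76, Nup154 at -1.72 and the importin gene msk at -1.36 (median -0.95, adjusted p = 0.00220, and adjusted p = 0.0911 with an estimated correlation). Splicing and 3' processing genes were lower in 11 of 15 and higher in 2 by both counts (median -0.41, adjusted p = 0.0371, and adjusted p = 0.205 with an estimated correlation), but did not pass against D. simulans (median -0.24, adjusted p = 0.157) or the parental mean (median -0.33, adjusted p = 0.0705). Aminoacyl tRNA synthetase genes were lower in 7 of 8 by both counts, among them GlnRS at -0.94 and CysRS at -0.89 (adjusted p = 0.0377, and adjusted p = 0.205 with an estimated correlation). The autophagy genes Atg9, Atg8a and Atg101 stood at 1.32, 1.11 and 1.03, while that list did not pass (4 of 6 higher and 1 lower by both counts, adjusted p = 0.284). Secretory pathway genes did not pass either (5 of 10 higher and 1 lower by both counts, adjusted p = 0.485).

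The 2 array series gave estimates that correlated across genes, which are not independent replicates, at 0.814 between the parents, 0.913 against D. melanogaster and 0.956 against D. simulans. A channel term passed the threshold in 439 genes (9.24%), 0 of them over 2-fold. The channel terms of the 2 series correlated at -0.11 across genes, so this term did not repeat between the series. With separate channel terms per series, 3495 genes lay outside both parents.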
